A study of Mus musculus with 30 samples.

How the data were processed

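RNA was sequenced from adipose-derived stem cells of inguinal fat of 30 male C57BL6/J mice. The cells carried Sca-1 and CD34, lacked CD31, CD45 and Ter119, and were expanded in culture to passage 2. Lean mice ate control chow and obese mice a diet with 60% of its energy from fat, given from weaning, and mice were killed at 20 weeks (young) or 52 weeks (aged). Aged obese mice had thus eaten this diet for longer than young obese mice. In obese mice age therefore cannot be told apart from time on the diet, and the same holds for differences of the obesity effect between ages. Groups and mouse numbers were taken from the sample titles, which gave 8 young lean, 8 young obese, 8 aged lean and 6 aged obese mice with 1 library each. The sample overview named no batch, date or sequencing lane, so a batch term could not be fitted.

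The deposited table held raw counts of reads per Ensembl mouse gene, whole numbers that were not normalized. Per the submitters' processing notes, STAR, HTSeq 0.7.0 and DESeq2 1.12.4 were used. The genome build, the annotation release, the version of STAR and the strand setting of the counting were not given in the sources used here, so no coordinates are printed. The table had 38561 genes and 5 lines that named no gene, which were left out of library sizes and tests. Of all counted reads, those in no gene made up 3.94% to 8.75% and ambiguous reads 2.69% to 3.41% per library. A symbol was found for 36639 of the identifiers and not for 1922. Reads of genes with near-identical copies, such as the ribosomal protein genes with their pseudogenes, and reads of overlapping or antisense genes may have been split or lost by the counting, so single values of such genes are uncertain.

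Counts in genes ranged from 30597765 in young lean 26 to 47970233 in aged obese 16, and levels are given as CPM, counts relative to these totals after scaling. Libraries of a group were compared pairwise with a chi-square statistic per gene, which lay between 6.79 and 516, so no pair agreed within sampling noise. Some libraries of a group lay much closer together than others. The statistic was 8.75 for young obese 1 and 2. Among young obese 18, 19, 20, 21 and 23 it lay between 6.79 (19 and 21) and 23.7 (20 and 23). Between such sets it was larger, 205 for 1 and 19 and 398 for 1 and 22. For aged obese 10 and 12 it was 78.8 and for 15 and 17 it was 80.0, against 516 for 10 and 17. The tests treat libraries of a group as independent, which such sets may not be. In edgeR 4.0.16 (R 4.3.3), genes were filtered with filterByExpr by group, which left 14438 genes, and libraries were scaled with TMM. A quasi-likelihood model with a term per group was fitted to all 30 libraries, so that all comparisons shared an estimate of the spread. Aged obese libraries spread more widely (median SD of log2 CPM 0.383, against 0.264 to 0.298 in the other groups). The shared estimate may therefore be too small for comparisons with aged obese libraries, and their calls too many. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Fold changes are given as log2 with their SE, levels as mean CPM with SD. The comparisons were age in lean mice, age in obese mice, obesity in young mice, obesity in aged mice, aged obese against young lean, and the difference of the obesity effect between ages (interaction).

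Of 44 gene lists written for pathways, cell types and checks, 40 were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. With the preset correlation 11 lists were called for age in lean, 21 for age in obese, 5 for obesity in young, 13 for obesity in aged, 15 for aged obese against young lean and 13 for the interaction, and with the estimated correlation 0 of these 78 calls remained. The estimated correlation was 0.859 for the ribosomal protein list and 0.556 for oxidative phosphorylation, far above the preset. Adjusted p with the preset correlation may therefore be far too small for such lists. Separation of groups was tested with a pseudo-F over all tested genes and an exact one-sided permutation of the library labels, adjusted over 5 comparisons. Correlations of fold changes between comparisons were computed across genes, which are not independent replicates.

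The genes named were the 8 with the largest rise and the 8 with the largest fall among called genes with a mean of at least 4 CPM and a symbol that was not a clone or predicted name (5 each way for the combined comparison and the interaction), up to 4 members with the smallest adjusted p of each list called, and the genes that served as keywords of the study or as sort markers. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined. The rule named 140 calls. Those described with values were chosen after the values were seen, mainly because they held, or nearly held, with each single library left out, and some named genes are not reported here.

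The alternatives fixed in advance were RLE scaling, no filter, a filter of at least 1 CPM in 6 libraries, DESeq2 1.42.0, limma voom with quality weights, 1 surrogate variable (sva 3.50.0), only the 2 groups compared in the fit, the mouse number as a block, each library left out in turn, and for the correlations Spearman's coefficient, a minimum of 10 CPM and split controls. Alternatives chosen after seeing the data were an offset per library for GC content and transcript length, the same offset fitted outside 2 lists, the mean of the cell cycle genes as a covariate, and fits without 2 young obese, 2 aged obese or 3 aged libraries. The offset was fitted with a spline (mgcv 1.9.3) on the longest transcript of each gene in GENCODE, and 14297 of the 14438 tested genes (99%) had a length and GC content. The test was tried on simulated counts with 200 changed genes. Of genes changed 2-fold it recovered 72% for age in lean, 66% for age in obese, 75% for obesity in young, 71% for obesity in aged and 55% for the combined comparison, and of genes changed 4-fold 94%, 94%, 93%, 87% and 95%, with 2.35% to 4% of calls false. Simulated genes were drawn independently, without the structure that genes and libraries share in the real data. Each gene had the same spread in all simulated groups, without the wider spread of aged obese libraries. The interaction was not simulated. The share of false calls in the real data may therefore be higher.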

Results

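Transcripts of cultured adipose-derived stem cells were counted in 30 libraries from young and aged, lean and obese mice. Counts in genes ranged from 30597765 in young lean 26 to 47970233 in aged obese 16, and 1 library came from each mouse. The first 2 principal components held 31.6% and 16.8% of the variance. The median SD of log2 CPM within a group was 0.383 in aged obese libraries, against 0.298 in aged lean, 0.292 in young lean and 0.264 in young obese libraries. Ly6a and Cd34, which encode the sorted markers Sca-1 and CD34, passed in none of the comparisons (smallest adjusted p = 0.303 for Ly6a and 0.655 for Cd34). Cd34 differed widely between libraries of a group, from 4.8 to 22.6 CPM in young lean, 0.91 to 27.9 in young obese, 1.07 to 28.7 in aged lean and 0.19 to 38 in aged obese libraries.

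**Figure D1:**
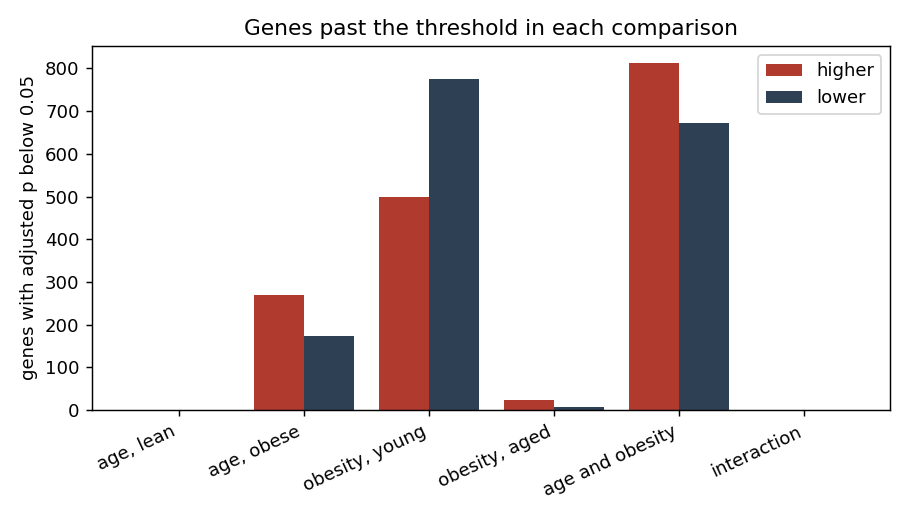
Number of genes with an adjusted p below 0.05 (vertical axis) in each comparison, higher and lower bars apart. Obesity in young mice had 499 genes higher and 776 lower, age in obese mice 270 and 173, aged obese against young lean 812 and 671, obesity in aged mice 24 and 8, and age in lean mice none.

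With obesity in young mice Ptn (ENSMUSG00000029838), which encodes the growth factor pleiotrophin, fell from 18.9 ± 12.9 CPM in 8 young lean to 2.4 ± 0.68 CPM in 8 young obese libraries (log2 fold change -2.98 ± 0.58, adjusted p = 0.00972), with no overlap between the groups. Agt, the precursor of angiotensin, fell by 2.32, Rspo2, an enhancer of Wnt signalling, by 1.86 and Ctla2a by 1.72 on the log2 scale. In the small fits of only the libraries with shared mouse numbers, the change of Agt was not negative. Vgf, the precursor of secreted neuropeptides, rose from 7.25 ± 3.77 to 21.9 ± 7.28 CPM (log2 1.59 ± 0.29, adjusted p = 0.00884), higher in 8 of 8 libraries than the lean median. Alkaline phosphatase Alpl rose by 1.79, Flt1, a receptor of vascular endothelial growth factor, by 1.55, Parm1 by 1.33 and the activin subunit Inhbb by 0.70. Without young obese 1 and 2 the call of Flt1 ended (adjusted p = 0.0769). Cd34 was at 26.1 and 27.9 CPM in these libraries and at 0.91 to 2.79 CPM in the other 6 young obese libraries.

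Of 76 cytosolic ribosomal protein genes 55 fell with obesity in young mice and 0 rose (74 fell adjusted over the list alone), with a median log2 change of -0.44. The list was lower with adjusted p = 2.59e-24, and adjusted p = 0.717 with an estimated correlation. Of 73 genes of oxidative phosphorylation 41 fell (59 adjusted over the list alone), with a median of -0.36 (adjusted p = 3e-18, and adjusted p = 0.717 with an estimated correlation). Rpl36 fell from 506 ± 170 to 332 ± 15.3 CPM (log2 -0.61 ± 0.14, adjusted p = 0.0172) and Ndufa1, a subunit of complex I, from 41.1 ± 10.2 to 27.3 ± 3.42 CPM (log2 -0.59 ± 0.13, adjusted p = 0.0151). With an offset for GC content and length the medians were -0.17 and -0.08, 3 and 6 genes fell, and Rpl36 (adjusted p = 0.139) and Ndufa1 (0.105) no longer passed. With no filter on low counts 5 and 6 genes fell, with medians of -0.42 and -0.34, and with only the young groups in the fit 24 genes of oxidative phosphorylation fell. The number of ribosomal protein genes that fell was 18 without young lean 23, 1 without young lean 26, 6 without young lean 27, 4 without young lean 7, 11 without young obese 1, 10 without young obese 2, 36 without young obese 19, 21 without young obese 20, 18 without young obese 21, 27 without young obese 22 and 33 without young obese 23. For oxidative phosphorylation it was 20, 1, 4 and 2 without young lean 23, 26, 27 and 7, and 7, 10 and 23 without young obese 1, 2 and 21. With single libraries left out the medians ranged from -0.49 to -0.33 for ribosomal protein genes and from -0.40 to -0.27 for oxidative phosphorylation, both smallest in size without young lean 26. Without both young obese 1 and 2 the medians were -0.44 and -0.28 and 0 genes of either list fell. Rpl36 was then at log2 -0.61 ± 0.16 (adjusted p = 0.0547) and Ndufa1 at -0.50 ± 0.14 (0.0618), and their calls ended. These transcripts were short (median length 1100 and 1141 bases, against 3222 for all tested genes), and the length dependence of the libraries was -0.0814 ± 0.14 log2 per doubling of length in young lean and 0.0754 ± 0.0819 in young obese libraries (n = 8 each, exact permutation p = 0.0152, two-sided, adjusted 0.076 over 5 comparisons).

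**Figure D2:**
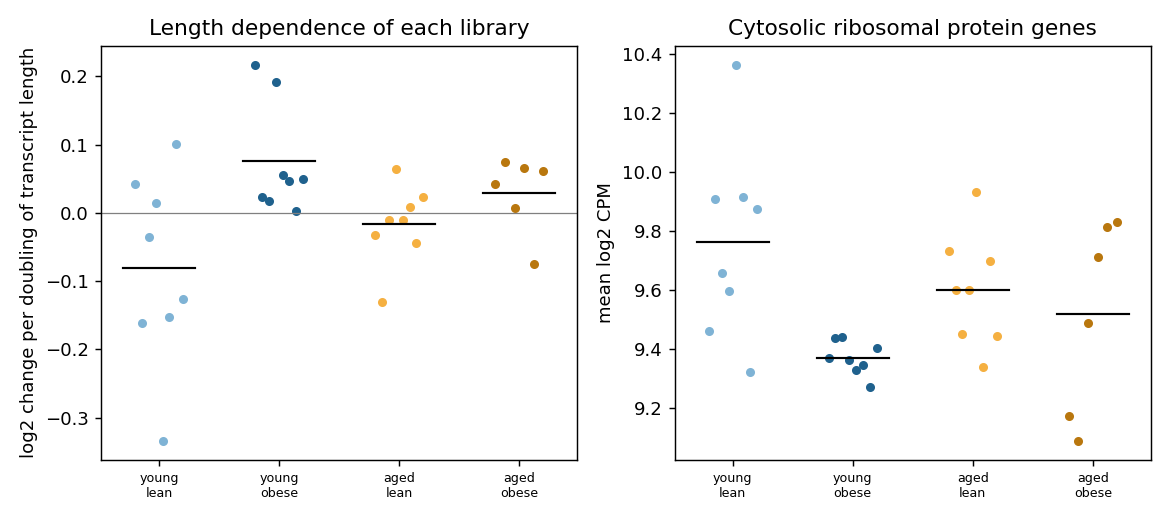
Left, change in log2 CPM per doubling of transcript length in each library; right, mean log2 CPM of the 76 cytosolic ribosomal protein genes in each library. Points are libraries by group and lines group means; the lowest slope was -0.334 in young lean 26, and the highest 0.217 in young obese 1.

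Genes of the unfolded protein response were higher in young obese cells, where 5 of 29 rose and 0 fell (5 rose and 1 fell adjusted over the list alone), with adjusted p = 0.000571 for the list and adjusted p = 0.717 with an estimated correlation. The co-chaperone Dnajc3 rose from 150 ± 15.7 to 194 ± 25.5 CPM (log2 0.37 ± 0.08, adjusted p = 0.0123). The offset for GC content and length (adjusted p = 0.052) and leaving out young obese 1 and 2 (0.0588) ended the call of Dnajc3. Of 24 genes of cholesterol synthesis 3 rose (6 adjusted over the list alone; adjusted p = 0.000322, and adjusted p = 0.917 with an estimated correlation). Of 25 genes of TGF-beta and activin signalling 3 rose (3 adjusted over the list alone; adjusted p = 0.00241, and adjusted p = 0.717 with an estimated correlation). In all, edgeR called 1275 genes, 499 higher and 776 lower, with a median size of 0.47 on the log2 scale, and the groups differed over all genes (pseudo-F 2.64, exact permutation p = 0.00793, adjusted 0.0392). Over the 500 most variable genes this did not pass (adjusted 0.0782). The count was 716 without young lean 23, 201 without young lean 26, 322 without young lean 27, 302 without young lean 7, 2040 without young lean 1, 2197 without the young lean library YL512, 405 without young obese 1, 485 without young obese 2, 713 without young obese 21 and 826 without young obese 22. It was 442 with the offset for GC content and length and 143 without young obese 1 and 2.

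With obesity in aged mice Sfrp2 (ENSMUSG00000027996), a secreted modulator of Wnt signalling, rose from 6.06 ± 2.22 CPM in 8 aged lean to 26.8 ± 13.7 CPM in 6 aged obese libraries (log2 2.15 ± 0.36, adjusted p = 0.00871). Rasl12 rose by 1.29 and the chemokine Ccl9 by 1.15 on the log2 scale, and all 3 genes were higher in 6 of 6 aged obese libraries than the lean median. Tnn, an extracellular matrix protein of the tenascin family, rose with a log2 change of 4.80 ± 0.81 (adjusted p = 0.00871), from a median of 1.56 CPM to 4.44 CPM with a range of 1.7 to 155 CPM. Its call ended without aged obese 10 and 12 (log2 1.03, adjusted p = 0.27) and with quality weights (0.207). Without those libraries the calls of Sfrp2 (adjusted p = 0.0504), Rasl12 (0.0504) and Ccl9 (0.076) ended as well. Ly6a was at 176.5 and 362 CPM in aged obese 10 and 12, against 917 to 1019 CPM in the other 4 aged obese libraries. Cd34 was at 0.19 and 0.73 CPM, against 9.67 to 38 CPM and 1.07 to 28.7 CPM in aged lean libraries. With only the aged groups in the fit, adjusted p was 0.0779 for Sfrp2, Rasl12 and Ccl9 and 0.18 for Tnn.

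The adhesion molecule Icam1 rose by 1.35 with obesity in aged mice (adjusted p = 0.0113). Without aged obese 10 its log2 change was 1.13 ± 0.24 and the call ended (adjusted p = 0.051), as it did without aged obese 10 and 12 (0.94 ± 0.24, adjusted p = 0.105), with quality weights (0.0546) and with only the aged groups in the fit (0.18). Trib3, a pseudokinase of the stress response, fell by 1.84 (adjusted p = 0.0312), and its call ended without each of these libraries except aged lean 11, 15 and 16 and aged obese 14 and 16 (adjusted p up to 0.095). Its log2 change lay between -1.83 and -1.66 in the fits that ended the call. Of 13 mural cell genes 0 passed and 3 rose adjusted over the list alone, with a median log2 change of 0.61 (list adjusted p = 0.000524, and adjusted p = 0.374 with an estimated correlation). Of the 25 genes of TGF-beta and activin signalling 0 passed and 8 rose adjusted over the list alone (adjusted p = 1.53e-05, and adjusted p = 0.586 with an estimated correlation). Of 30 immediate early genes and genes induced by cell dissociation 0 passed (0 adjusted over the list alone), and 28 were positive, with a median of 0.46 (list adjusted p = 1.53e-05, and adjusted p = 0.752 with an estimated correlation). In all, 32 genes were called, 24 higher and 8 lower, and the separation of the groups over all genes did not pass (pseudo-F 1.27, exact permutation p = 0.247, adjusted 0.309). The count was 13 without aged lean 12, 15 without aged lean 13, 435 without aged lean 16, 11 without aged lean 17, 12 without aged lean 19, 17 without aged lean 20, 9 without aged obese 10, 17 without aged obese 12, 318 without aged obese 16 and 54 without aged obese 17. With only the aged groups in the fit 0 genes passed in edgeR, against 32 in the fit of all groups, where 1838 had an unadjusted p below 0.05. In fits of all groups DESeq2 called 187 genes and voom 114.

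**Figure D3:**
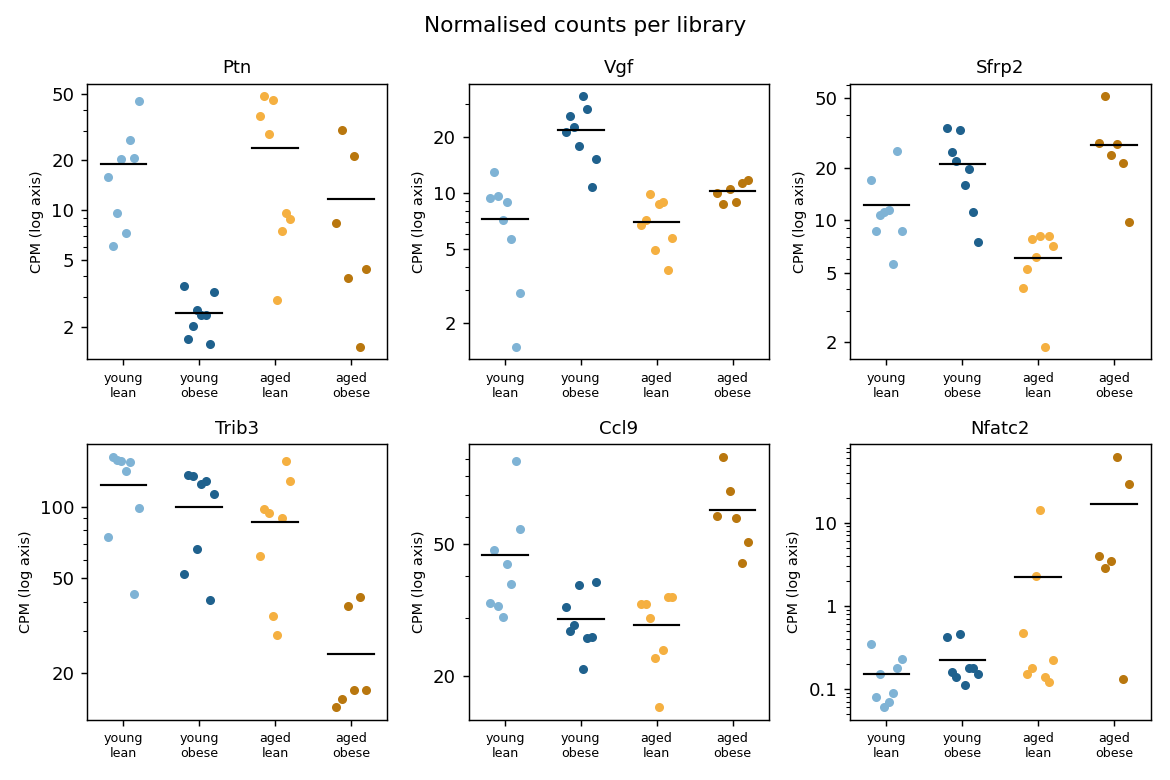
CPM (log axis) of 6 genes in each library of the 4 groups; lines are group means. Ptn was lowest in young obese (mean 2.4 CPM), Trib3 in aged obese libraries (24.1 CPM), Sfrp2 was higher in aged obese (26.8 CPM) than in aged lean (6.06 CPM), and Nfatc2 in aged obese libraries ranged from 0.13 to 61.8 CPM.

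With age in lean mice 0 genes passed in edgeR, with 773 genes (5.35%) at an unadjusted p below 0.05 and a smallest adjusted p of 0.0932. DESeq2 called 8 genes, 6 higher and 2 lower, and voom with quality weights 6. The keyword gene Nfatc2 did not pass (adjusted p = 0.85), with medians of 0.12 CPM in young lean and 0.204 CPM in aged lean libraries. Its log2 change was 3.80 ± 1.07, and 1.71 ± 0.89 without aged lean 16, which was at 14.1 CPM. The ribosomal protein list was lower, with 0 of 76 genes passing, a median of -0.19 (0 adjusted over the list alone; adjusted p = 6.66e-11, and adjusted p = 0.86 with an estimated correlation). Genes of TGF-beta and activin signalling were higher as a list, with 0 of 25 passing, a median of 0.18 (0 adjusted over the list alone; adjusted p = 8.65e-05, and adjusted p = 0.86 with an estimated correlation). The separation of the lean groups by age did not pass (pseudo-F 1.11, exact permutation p = 0.313, adjusted 0.313). Without aged lean 13, without young lean 23 or without young lean 27 the count was 1.

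With age in obese mice Trib3 (ENSMUSG00000032715) fell from 99.4 ± 39.7 CPM in 8 young to 24.1 ± 12.5 CPM in 6 aged libraries (log2 -2.04 ± 0.39, adjusted p = 0.00745), lower in 6 of 6 libraries than the young median. Stc2, a secreted glycoprotein hormone, fell by 1.48 and the transcription factor Tcfl5 by 1.27 on the log2 scale. Nfatc2 (ENSMUSG00000027544), a transcription factor of the calcineurin pathway and a keyword of the study, rose with log2 6.24 ± 1.1 (adjusted p = 0.00585), from a median of 0.169 CPM (0.109 to 0.461) to 3.69 CPM (0.13 to 61.8). Heyl and Hey1, transcription factors downstream of Notch, and the Notch ligand Jag1 rose with log2 10.38, 6.09 and 3.85. Heyl had 6 counts in all young obese libraries together, so its log2 change depends on the prior count, and in aged obese libraries its median was 5.14 CPM (0.0428 to 135). Jag1 had medians of 13.2 and 45.6 CPM. Aged lean 16 had Heyl at 47.1, Hey1 at 57.9 and Jag1 at 388 CPM, where the aged lean medians were 0.19, 0.994 and 16.3 CPM. Without aged obese 15 the log2 changes of Hey1 and Jag1 were 5.28 ± 1.24 and 2.99 ± 0.79 and their calls ended (adjusted p = 0.0556 and 0.0921). With the cell cycle genes as a covariate they were 2.79 ± 1.03 and 1.73 ± 0.60 (adjusted p = 0.114 and 0.0935). The keyword genes Cd44, a receptor of hyaluronan (log2 0.97 ± 0.28, adjusted p = 0.0498), and Dusp6, a phosphatase that acts on ERK (log2 1.26 ± 0.35, adjusted p = 0.0458), rose by narrow margins. The call of Cd44 ended without each library of these groups except aged obese 14 and 16 and young obese 22 (adjusted p up to 0.173), and that of Dusp6 without each except aged obese 16 and young obese 1 and 2 (up to 0.115). Both highest values came without aged obese 15, where the log2 change was 0.81 ± 0.28 for Cd44 and 1.27 ± 0.37 for Dusp6.

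Of 25 genes of TGF-beta and activin signalling 5 rose with age in obese mice (10 adjusted over the list alone; list adjusted p = 0.00519, and adjusted p = 0.582 with an estimated correlation). Of the 13 mural cell genes 11 were positive and 1 rose (2 adjusted over the list alone; list adjusted p = 0.22, and adjusted p = 0.641 with an estimated correlation). It was the pericyte proteoglycan Cspg4, named after its values were seen (log2 2.04 ± 0.47, adjusted p = 0.0223, and 1.43 ± 0.44, adjusted p = 0.12, without aged obese 15). Of the 30 immediate early and dissociation genes 2 rose (4 adjusted over the list alone; adjusted p = 0.00241, and adjusted p = 0.621 with an estimated correlation). Of 29 genes of the unfolded protein response 3 fell, Trib3 among them (5 adjusted over the list alone; adjusted p = 0.0023, and adjusted p = 0.582 with an estimated correlation). All 76 ribosomal protein genes were positive, with a median of 0.17 and 0 passing (0 adjusted over the list alone; adjusted p = 1.55e-05, and adjusted p = 0.641 with an estimated correlation). Of 47 genes of the interferon response 1 rose (1 adjusted over the list alone; adjusted p = 8.41e-07, and adjusted p = 0.582 with an estimated correlation). It was Ifi35, at log2 0.69 (adjusted p = 0.0273), and its call ended without aged obese 15 (0.119) and 17 (0.0582). In all 443 genes were called, 270 higher and 173 lower, and the separation of the groups over all genes did not pass (pseudo-F 2.0, exact permutation p = 0.0839, adjusted 0.14). The count was 693 without aged obese 10, 43 without aged obese 15, 1027 without aged obese 16, 159 without aged obese 17, 283 without young obese 2, 222 without young obese 18, 169 without young obese 19, 222 without young obese 20, 184 without young obese 21 and 183 without young obese 23. With only the obese groups in the fit it was 181.

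Aged obese cells against young lean cells had Cd44 (ENSMUSG00000005087) at 508 ± 238 CPM (n = 6) against 198 ± 37.7 CPM (n = 8), a log2 change of 1.36 ± 0.28 (adjusted p = 0.00661). The ERK phosphatase genes Dusp6 and Dusp4 rose by 1.71 and 2.69, the hyaluronan synthase Has2 by 1.56 and the clock repressor Nr1d1 by 1.16 on the log2 scale. Trib3 fell by 2.36 and the amino acid transporter Slc38a4 by 2.17. Nfatc2 rose with log2 6.76 ± 1.16 (adjusted p = 0.0036), from a median of 0.12 CPM (0.0591 to 0.355) to 3.69 CPM (0.13 to 61.8). It was higher in 6 of 6 aged obese libraries than the young lean median, but the ranges overlapped. Of the 51 named calls here 31 held with each single library left out. With quality weights the calls of Cd44 (adjusted p = 0.0535) and Dusp4 (0.0518) ended. The keyword gene Itih2 passed in none of the comparisons (smallest adjusted p = 0.193).

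Of 25 genes of TGF-beta and activin signalling 13 rose in aged obese against young lean cells and 0 fell (15 rose adjusted over the list alone; list adjusted p = 1.12e-07, and adjusted p = 0.312 with an estimated correlation). Among them were Acvr1, a receptor of the family (log2 0.55 ± 0.10, adjusted p = 0.0036), Pmepa1 (0.92 ± 0.19, adjusted p = 0.00692) and Tgfb3 (1.49 ± 0.31, adjusted p = 0.00668). The call of Tgfb3 ended with quality weights (adjusted p = 0.181) and without aged obese 10 and 12 (0.056). Of the 13 mural cell genes 2 rose (3 adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.696 with an estimated correlation). They were Cspg4 (1.5 ± 0.47, adjusted p = 0.0378) and the smooth muscle myosin Myh11 (1.2 ± 0.39, adjusted p = 0.0467). The call of Cspg4 ended without each of 8 single libraries (aged obese 10, 12 and 15 and young lean 23, 24, 25, 26 and 27; adjusted p up to 0.216). That of Myh11 ended without each of 10 (aged obese 10, 12, 14 and 15 and young lean 1, 7, 24, 26, 27 and YL512; up to 0.131). Of the 30 immediate early and dissociation genes 2 rose (2 adjusted over the list alone; adjusted p = 0.00019, and adjusted p = 0.696 with an estimated correlation). Of 24 genes of cholesterol synthesis 8 rose (10 adjusted over the list alone; adjusted p = 3.39e-06, and adjusted p = 0.696 with an estimated correlation), among them Insig1 (0.86 ± 0.22), Hsd17b7 (0.95 ± 0.21) and the transcription factor Srebf2 (0.41 ± 0.10). Of 18 genes of ERK feedback 4 rose (5 adjusted over the list alone; adjusted p = 0.00144, and adjusted p = 0.696 with an estimated correlation). Of 17 clock genes 6 rose (9 rose and 1 fell adjusted over the list alone; adjusted p = 0.00668, and adjusted p = 0.696 with an estimated correlation). In all 1483 genes were called, 812 higher and 671 lower (pseudo-F 2.37, exact permutation p = 0.0157, adjusted 0.0392, and 0.0782 over the 500 most variable genes). The count was 642 without aged obese 15, 2405 without aged obese 16 and 826 without aged obese 17. With quality weights it was 695, and with only these groups in the fit 410.

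Ccl9 (ENSMUSG00000019122) was the 1 gene called by the interaction test, which compares the effect of obesity between ages. The median SE of this test was 0.241, against 0.164 to 0.178 in the other comparisons, so differences of other genes may have been missed. Ccl9 was at 46.2 ± 19.2 CPM in young lean and 29.7 ± 6.04 CPM in young obese libraries (log2 -0.63 ± 0.20, adjusted p = 0.0425), and at 28.5 ± 6.81 and 63.1 ± 16.8 CPM in aged lean and aged obese libraries (log2 1.15 ± 0.21, adjusted p = 0.0113). The difference was 1.78 ± 0.29 on the log2 scale (adjusted p = 0.0131), and 1155 genes had an unadjusted p below 0.05. The ribosomal protein list passed in the interaction with the preset correlation (median 0.37, 0 of 76 genes passing, 0 adjusted over the list alone, adjusted p = 3.27e-18). With an estimated correlation it did not pass (adjusted p = 0.694). The count was 6 without aged lean 16, 2 without aged lean 17, 4 without aged obese 16, 3 without aged obese 17, 3 without young lean 1 and 2 without young lean 23. DESeq2 called 7 genes and voom with quality weights 91.

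Fold changes of obesity in young and in aged mice, which share no library, had a Pearson correlation of 0.367 across 14438 genes (Spearman 0.439, covariance 0.0547). Of the 1275 genes called in young mice 1116 had the same sign in aged mice. Both sets of calls shared 4 higher genes, where independent lists would share 0.83, and 1 lower gene, where they would share 0.43. Fold changes of age in lean and in obese mice had r = 0.423 (Spearman 0.253, covariance 0.0569). Age in lean and obesity in young mice were both measured against the young lean libraries and had r = 0.365 (covariance 0.0416), where unchanged simulated groups gave a mean r of 0.503 (covariance 0.0329, 20 draws). With the young lean libraries split between the comparisons, mean r was 0.067, from -0.201 to 0.363, with a covariance of 0.0074.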

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

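The tests of a single aged obese library and of endothelial and of mural cells were chosen after the result was seen, and the cell cycle covariate after the data were seen.

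Over 20 measures, 80 groups were searched for a library far from the others, and 5 were found, where chance gives about 1 in 20 groups. Young obese 22 lay at -7.7 on the fourth principal component, where the other young obese libraries lay between 17 and 24, and had Cd44 at 413 CPM, against 214 to 271 CPM. Aged lean 16 had Cd44 at 611 CPM, against 142 to 359 CPM in the other aged lean libraries, and Nfatc2 at 14.1 CPM, against 0.124 to 2.25 CPM. Young obese 1 had Ly6a at 550 CPM, against 689 to 811 CPM. Between ages, the log2 change of Ccl9 with obesity differed by 1.78 by the interaction test.

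Nfatc2, Heyl, Hey1 and Jag1 were higher with age in obese mice and ranged widely among the aged obese libraries, and some aged lean libraries were high as well (Hey1 at 57.9, 22.5 and 15.8 CPM in aged lean 16, 15 and 11, against at most 0.67 CPM in young obese libraries). Endothelial cells were argued against as the whole source, since the higher of Pecam1 (0.0935 CPM) and Cdh5 (0.333 CPM) reached a ratio of 0.0102 to Heyl (32.6 CPM) and the sort had removed cells with CD31, but mural cells stayed open, with Rgs5 at 1.46 CPM and a median log2 change of 0.27 over 13 mural genes, 11 of them positive and 1 (Cspg4) higher. A single library was argued against as the whole source, since with each aged obese library left out the smallest of the 4 log2 changes was 3.77 times its error (Jag1, 2.99 ± 0.79 without aged obese 15), but a share of aged obese 15 stayed open, because 2 of the 4 genes passed without it and all 4 without each other aged obese library. Leaving out 1 library cannot address a source in 2 similar libraries, such as aged obese 15 and 17 (chi-square of 80.0 per gene). Growth state stayed open as well, since with the cell cycle genes as a covariate 2 of the 4 passed, and Hey1 went from 6.09 ± 1.27 to 2.79 ± 1.03 (adjusted p = 0.114) and Jag1 from 3.85 ± 0.84 to 1.73 ± 0.60 (adjusted p = 0.0935), the fold falling more than its error. Age itself, and the longer time on the diet that came with it, remain untested explanations that cannot be told apart.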

How the results depend on the processing

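The offsets, the cell cycle covariate, the fits without 2 or 3 libraries, the estimated correlation without aged obese 10 and 12, and the fit of the shared numbers without a block were chosen after the data were seen; the 3 aged libraries were picked by their Nfatc2 level, so no weight is placed on that fit. Counts are given in the order age in lean, age in obese, obesity in young, obesity in aged, aged obese against young lean, and interaction, with 0, 443, 1275, 32, 1483 and 1 called. They were 0, 447, 1221, 32, 1562 and 1 with RLE scaling, 0, 436, 1399, 22, 1461 and 1 with the stricter filter, and 0, 253, 371, 18, 1049 and 1 with no filter, where more genes are tested. DESeq2 called 8, 855, 1810, 187, 2075 and 7 genes, voom with quality weights 6, 2870, 4266, 114, 695 and 91, and a fit with 1 surrogate variable 0, 865, 2985, 173, 2934 and 6. With only the groups compared the first 5 were 0, 181, 1642, 0 and 410. The offset gave 0, 508, 442, 66, 1618 and 3, that fitted outside 2 lists 0, 514, 440, 66, 1627 and 3, and the cell cycle covariate 0, 540, 2700, 170, 2742 and 5. Without young obese 1 and 2 the counts were 0, 643, 143, 49, 1771 and 4, without aged obese 10 and 12 they were 0, 2679, 1852, 9, 1513 and 5, and without aged obese 15 and 17 and aged lean 16 they were 0, 89, 1666, 98, 532 and 1. With single libraries left out they ranged from 0 to 1, 43 to 1027, 201 to 2197, 9 to 435, 642 to 2405 and 1 to 6. Apart from the number of genes or libraries, the cause was not tested.

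Of the 140 named calls 138 held with RLE scaling, 106 with no filter, 140 with DESeq2, 111 with voom, 138 with a surrogate variable, 113 with the offset, 123 with the cell cycle covariate, 78 (of 138) with only the groups compared and 80 without the 3 aged libraries. Etv4 turned to -0.10 in aged obese against young lean without aged obese 10 and 12, and Dlx3 to -0.26 without the 3 aged libraries. Of 78 list calls 0 held with an estimated correlation and 40 with the cell cycle covariate, which called 42. The list of cytosolic ribosomal proteins turned upward for obesity in aged mice without aged obese 10 and 12 (adjusted p = 0.000493, and adjusted p = 0.684 with an estimated correlation, which called 0 lists there). The correlation of age effects was 0.253 by Spearman, and that of age and obesity effects 0.067 with split controls. Over the 500 most variable genes the adjusted p of the group separation was 0.0782 both for obesity in young mice and for aged obese against young lean.

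Mouse numbers shared between groups (1 and 23 in young, 12, 15, 16 and 17 in aged) did not pair the libraries: deviations correlated at 0.082 and 0.215 in young and at 0.199, 0.39, -0.099 and -0.517 in aged mice, and no library correlated best with its own number. With the number as a replicate block over these libraries obesity had 0 calls by edgeR at either age, as without the block. The full fit of all 30 libraries had 1275 and 32 calls, and 4091 and 1838 genes at an unadjusted p below 0.05. Of 46 named calls 0 held in either of these small fits, and 3 for obesity in young mice turned, Agt to 0.017 with the block and 0.054 without it, Aspn to 0.94 and 0.59 and Kng1 to 0.21 and 0.30. A batch term was not run. Genes such as Heyl were barely counted in some groups, with 6 counts over all young obese libraries.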

Other observations

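The tests with an offset, with the cell cycle covariate and without young obese 1 and 2 were chosen after the data were seen, but before the values they measure.

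Of 42 cell cycle genes 0 passed with age in obese mice by edgeR, and 3 were positive, with a median log2 change of -0.33 (0 adjusted over the list alone; adjusted p = 0.0023, and adjusted p = 0.651 with an estimated correlation). Of 32 genes of hypoxia and glycolysis 2 fell, Pfkfb3, an activator of glycolysis (log2 -1.37 ± 0.32, adjusted p = 0.0226), and the oxygen sensor Egln3 (-1.10 ± 0.26, adjusted p = 0.0238), and adjusted over the list alone 3 fell and 1 rose (list adjusted p = 0.000343, and adjusted p = 0.621 with an estimated correlation). Without aged obese 15 neither Pfkfb3 (log2 -1.36 ± 0.35, adjusted p = 0.076) nor Egln3 (-0.96 ± 0.26, 0.0939) passed. Tet1, an enzyme of DNA demethylation, fell by 1.24 (adjusted p = 0.0165, and 0.0739 without aged obese 15). It was 1 of 2 genes that fell among 23 of the DNA methylation machinery (4 fell and 2 rose adjusted over the list alone; adjusted p = 0.0274, and adjusted p = 0.582 with an estimated correlation). Of the named calls 5 of 42 for age in obese mice held with each single library left out, 14 of 33 for obesity in young mice and 4 of 13 for obesity in aged mice.

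By 100 splits of the libraries each, chance was made less likely, but not excluded, as the source of some counts. For age in obese mice 443 genes were reached by 2 splits with the real one (highest other 1669). For obesity in young mice 1275 were reached by 1 (highest other 0). For aged obese against young lean 1483 were reached by 2 (highest other 1560). These shares were not adjusted over the comparisons. The splits moved libraries singly, so sets of close libraries, such as young obese 18, 19, 20, 21 and 23, may make chance look less likely than it is. Separation over all genes did not pass for age in obese mice (exact permutation p = 0.0839). The 1 gene of the interaction was reached by 4 (highest other 9), but those splits exchanged age labels among lean and among obese libraries. They ask whether age had any effect, not whether the obesity effect differed, so chance stayed open there. Nor could it be excluded for obesity in aged mice (32, by 15, highest other 2793). For age in lean mice the splits tested nothing, since each split has at least the 0 genes called (highest other 299). The splits with 1669 and 2793 genes, several times the real counts, point to a structure of the libraries, and what it was has not been tested.

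Ribosomal protein and oxidative phosphorylation transcripts were lower in young obese cells, with medians of -0.44 and -0.36. Without the pair of young obese libraries that stood apart the medians were -0.44 and -0.28, which argues against this pair as the whole cause. With the cell cycle covariate they were -0.41 and -0.37, which argues against cell cycle activity as the whole cause. Of 42 cell cycle genes 41 were positive in young obese cells and 0 passed, with a median log2 change of 0.365. The covariate does not measure other sides of growth state, which stay open. Length and GC bias between libraries cannot be told apart from an effect of obesity, since the offset, and one fitted outside these lists, left the ribosomal median at -0.17 and -0.18, between the bounds set in advance, and that of oxidative phosphorylation at -0.08 and -0.10, within the range set for such a bias as the cause. With the offset the number of genes that fell went from 55 to 3 and from 41 to 6, the median ratio of log2 change to error from -3.36 to -1.78 and from -3.22 to -1.19, and the largest unadjusted p called over all genes from 0.00441 to 0.00151. Obesity in young mice stays open as an explanation.

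More genes were called for obesity in young than in aged mice (1275 against 32), and the interaction test called 1. Without young obese 1 and 2 the ratio was 2.92 (143 against 49), only just under the bound of 3 set in advance, so that they may account for part of this. The lost calls do not single them out, since without young lean 26 alone the young count was 201, and without young lean 7 or 27 it was 302 or 322. The aged count also moved with single libraries, from 9 without aged obese 10 to 318 without aged obese 16 and 435 without aged lean 16. A wider spread in aged mice cannot be told apart. The SD of log2 changes after taking off the error was 0.756 times that in young mice, with a range of 0.617 to 1.05 over single libraries left out. The error came from the spread shared by all groups, though aged obese libraries spread more widely. Too little may thus have been taken off on the aged side, so this ratio cannot decide the question. Length and GC bias stayed open too, with a ratio of 6.7 under the offset.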
